A study of Saccharolobus islandicus REY15A with 4 samples.

How the data were processed

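RNA was measured by sequencing in 4 libraries of the thermoacidophilic archaeon Saccharolobus (Sulfolobus) islandicus REY15A. The groups were 2 libraries of the parental strain E234 and 2 of a strain derived from it without cbp1. Per the labels' protocols, cultures grew at 75 °C in shaken flasks with sucrose, tryptone and uracil. Total RNA was depleted of ribosomal RNA and fragmented. Fragments of 17 to 200 nt were treated with polynucleotide kinase, to make RNAs with blocked ends such as crRNAs ligatable, and converted to libraries with a small RNA kit and 12 cycles of PCR. Processed crRNAs and pieces of longer transcripts therefore entered the same libraries, and the counts do not tell them apart.

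The deposited table gives raw counts per annotated feature for each library, per the file headers. The submitters' processing notes name cutadapt 4.1, Bowtie 1.0.0, SAMtools, bedtools 2.30.0, featureCounts 2.0.6 and DESeq2 1.40.2, with no roles. The genome build, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of overlapping or antisense features, of transposase copies and of the CRISPR repeats are uncertain for that reason. The authors also deposited a mean normalized signal per feature, a log2 fold change with its standard error, a test score (the Wald statistic), a p-value and an adjusted p-value, per the file headers. The deposited mean signal was recomputed from the counts with median-of-ratios factors, and the deposited adjusted p-values equalled a Benjamini-Hochberg adjustment over all 2657 features.

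The count columns are numbered 1 and 2 for the parental strain and 2 and 3 for the deletion strain, while the sample titles number both groups 1 and 2. Columns were therefore assigned to groups only, and libraries are named here by their column numbers. The labels do not say whether the libraries of a group came from separate cultures. The p-values measure the spread between these libraries, which may be technical in part. In pairwise chi-square tests of the counts, the chi-square per degree of freedom was 39.7 between the parental libraries and 13.9 between the deletion libraries, so neither pair agreed within sampling noise and each library was counted once. It was 29.8 and 25.5 between parental library 2 and deletion libraries 2 and 3, and 81.9 and 60.3 between parental library 1 and these. By this measure parental library 2 was closer to the deletion libraries than to the other parental library, while the SD of log2 ratios was smaller within the parental pair (0.290) than between parental library 2 and the deletion libraries (0.341 and 0.325).

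Of the 2657 features, 2655 carried a product text. Names were taken from the RefSeq gene table of assembly ASM18955v1, for 2424 features by start and end and for 148 by the position of the stop codon. The other 85 kept the identifier of the table, and coordinates are those of the deposited table, for which no build is named. The 2 features without a product text lie on either side of the adaptation genes of the type I-A CRISPR-Cas locus and are treated as the 2 CRISPR arrays of the strain. That identity rests on their position and length and not on a label.

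The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts of all 4 libraries with TMM normalization and edgeR's default expression filter. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The filter removed 85 features with 0.00492% of the counts and left 2572. Fold changes are deletion over parental strain on the log2 scale, abundances are CPM values (counts scaled to a common library size with the TMM factors) given as mean ± SD of 2 libraries, and standard errors come from the quasi-likelihood F statistic. The common biological coefficient of variation was 0.0955. The fit was tested on simulated counts for 2657 features in this comparison, drawn at the means, library sizes and fitted dispersions of the real counts. In each of 5 runs, 200 features with a mean of at least 20 counts were changed. The fit recovered 71.3% of 1.5-fold, 96.4% of 2-fold and 99.7% of 4-fold changes, with 4.50% of calls false. Each simulated feature had the same dispersion in all libraries, while the real parental pair differed more than the deletion pair. DESeq2 1.42.0 was an alternative and gave the 108 calls of the authors' deposited table.

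Before the data were examined, 21 gene lists were defined by product text, and 18 had at least 3 tested members. List members among the called genes were counted, compared with other tested genes by Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over the lists), and tested with camera and fry of limma 3.58.1. A further 4 lists, for corrinoid and tetrapyrrole synthesis, riboflavin synthesis, sulfate assimilation and ABC transporters, were chosen after seeing the data. Named genes followed a rule written beforehand. It took the 12 largest rises and 12 largest falls among called genes with a mean of at least 20 normalized counts and no overlap between groups, up to 10 called members of the CRISPR-Cas list, strain markers, the 5 genes on each side of cbp1, and up to 4 members of each other list with the smallest adjusted p. Genes named outside this rule were chosen after their values were seen, and are marked so. Lowered features at most 10 listed features apart were joined into segments, a choice also made after seeing the data.

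Alternatives were DESeq2, RLE and upper quartile factors, no expression filter, a mean of at least 50 counts, library sizes without the arrays and the 10 most abundant features, stricter thresholds, runs of adjacent genes counted once, and each library left out in turn. Figures and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Values for cbp1, pyrF and lacS were not analysed here, so the deletion itself was not checked in these counts.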

Results

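The 4 libraries held 7521062 and 8133854 counts for the parental strain E234 (libraries 1 and 2) and 7645913 and 6555558 counts for the cbp1 deletion strain (libraries 2 and 3). Cbp1 is a small protein known for binding CRISPR repeats in Sulfolobales. The comparison of the strains asks how the transcriptome, the CRISPR arrays among it, differs without this protein. Values of cbp1 itself were not analysed here, so the genotype labels stand unchecked by the deleted gene. The 10 most abundant features took 22.0% to 23.0% of the counts in each library.

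Without cbp1, RNA from both CRISPR arrays fell by edgeR's test, while DESeq2 did not call the minus-strand array. In the stretch of chromosome that holds both arrays 38 of 61 tested features fell by edgeR's test, the arrays and 11 genes of the type I-A cas locus included. Outside this stretch the changes with the smallest adjusted p were in a divergent pair of neighbours. SiRe_1595, annotated as a cobyrinic acid a,c-diamide synthase of corrinoid synthesis, rose 3.49-fold, and pcn, which encodes a DNA polymerase sliding clamp, fell 2.60-fold. Most rises were smaller than 2-fold, and 9 of the raised genes were transporter genes. In total 85 of 2572 tested features were called by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 51 lower and 34 higher in the deletion strain, and 32 and 7 of them changed at least 2-fold. All 85 had both libraries of a strain above both of the other. So did 1035 (40.2%) of all tested features, where chance alone gives 33.3%. Of the calls, 79 were also among the 108 of the authors' deposited table. With groups of 2, the count depended on each library: it was 72 without parental library 1, 242 without parental library 2, 16 without deletion library 2 and 8 without deletion library 3.

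**Figure D1:**
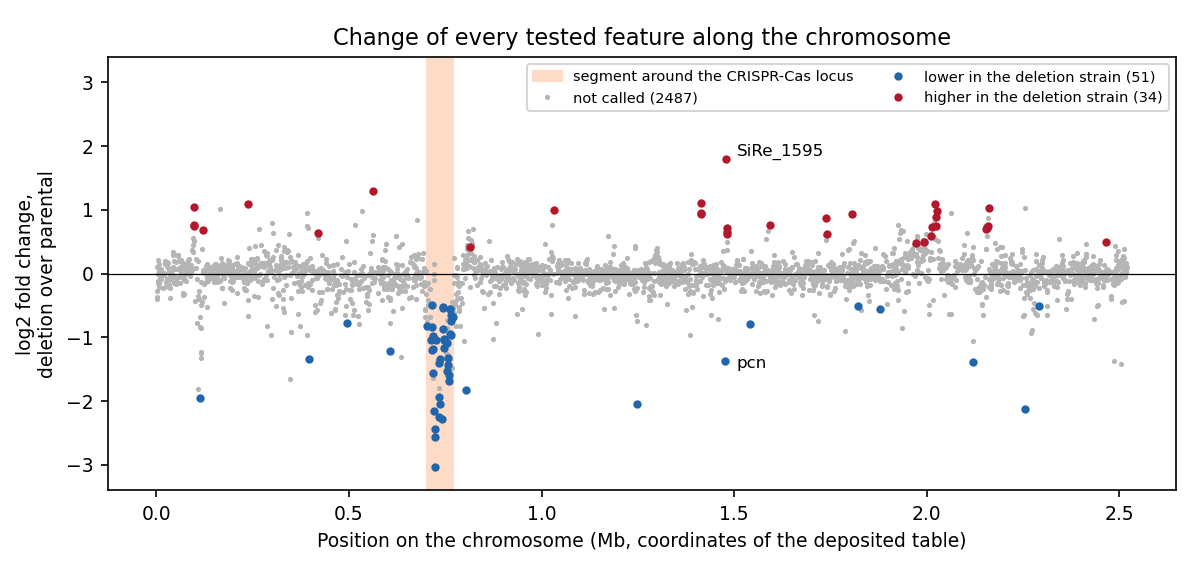
Log2 fold change (deletion over parental strain, 2 libraries each) of the 2572 tested features against their position in Mb. Grey points were not called, blue points are the 51 lower and red points the 34 higher features, and the shaded segment holds 38 of the lower ones.

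The array on the minus strand (725209 to 732590) gave 6815 ± 2480 CPM in the parental strain and 3299 ± 267 CPM in the deletion strain (SD, n = 2 each), a log2 fold change of −1.05 ± 0.20 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0227). The array on the plus strand (736642 to 742629) gave 17646 ± 5946 CPM and 6992 ± 556 CPM, a change of −1.34 ± 0.19 (edgeR adjusted p = 0.00583). The minus-strand array took 0.849% and 0.508% of the counts in parental libraries 1 and 2 but 0.311% and 0.351% in the deletion libraries, and the plus-strand array 2.16% and 1.35% against 0.660% and 0.744%. The parental libraries differed from each other in both arrays, and without parental library 1 the changes were −0.62 and −0.94. DESeq2 did not call the minus-strand array (adjusted p = 0.108), and neither array was called when either deletion library was left out (edgeR adjusted p from 0.0817 to 0.336).

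Of the 30 tested CRISPR-Cas genes, 11 fell and none rose by edgeR's quasi-likelihood test, and 13 fell when adjusted over the list alone. The falls were steepest in the adaptation genes, which serve spacer uptake, and in SiRe_0765. Among them cas1, the integrase endonuclease, fell from 25.8 ± 8.18 to 5.41 ± 0.0633 CPM (log2 −2.25 ± 0.27, edgeR adjusted p = 0.00249). SiRe_0764, annotated as the regulator Csa3, fell 4.13-fold, the Cas4 gene SiRe_0763 fell 3.82-fold and cas4a fell 2.64-fold. The gene SiRe_0765, which follows the plus-strand array, fell 4.85-fold. It shares the symbol csa3 with SiRe_0764, while its product text names only a CRISPR-associated protein. The interference genes downstream, which are more abundant, fell by smaller folds. The backbone gene cas7a fell from 922 ± 11.4 to 643 ± 68.0 CPM (log2 −0.52 ± 0.10, edgeR adjusted p = 0.0263). The genes csa5 (log2 −0.55), cas5a (−0.88) and the helicase gene cas3 (−1.17) fell as well. The remaining falls were in SiRe_0770 (Cas3'', −1.03) and, chosen after its value was seen, csaX (−1.04). In the same locus cas2 (−1.79 ± 0.45, edgeR adjusted p = 0.0743) and cas6 (−1.10 ± 0.30, edgeR adjusted p = 0.0944), also chosen afterwards, were not called. DESeq2 did not call cas4a (adjusted p = 0.0780).

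The other 17 CRISPR-Cas genes lie elsewhere on the chromosome and gave log2 fold changes of −0.30 to 0.30. None was called by edgeR's quasi-likelihood test (lowest adjusted p = 0.382) or by DESeq2, and 1 had an unadjusted p under 0.05. They include 12 cmr genes of the type III-B complexes, at −0.30 to 0.16. Whether these genes differ in response from those at the arrays was not tested as an interaction. The list held more lowered genes than other tested genes (Fisher's exact test, two-sided, p = 2.47e-12, Benjamini-Hochberg adjusted p = 4.45e-11). With runs of adjacent members counted once, 3 of 10 runs were lower (Fisher's exact test, p = 0.00316). The camera test with a preset correlation of 0.01 gave an adjusted p = 1.71e-10, and an adjusted p = 0.993 (unadjusted p = 0.0783) with an estimated correlation. The rotation test fry of limma gave a downward shift with adjusted p = 0.422 (unadjusted 0.0419). Without parental library 1 the count of lowered CRISPR-Cas genes was 7, and without deletion library 2 or 3 it was 2 or 1.

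Lowered features were concentrated between positions 702344 and 769850, a segment of 67.5 kb around the CRISPR-Cas locus. Of 61 tested features in it, 38 fell and none rose by edgeR's quasi-likelihood test, and 22 of the other 23 had log2 fold changes below 0. The median over the 61 was −1.03, against 0.00 over the 2511 tested features outside, of which 13 fell. The lowered features lay on both strands, 20 on plus and 18 on minus. On the left flank, 12 of 24 tested features fell, between the arrays 4 of 5, and on the right flank 20 of 30. The left edge is set by the transposase SiRe_0736 (log2 −0.82 ± 0.17), whose counts are uncertain like those of other transposases. The next lowered feature, aceA, starts at 712658. Without deletion library 2 or 3 the number of called features in the segment was 10 or 6.

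The segment includes genes of metabolism beside the cas genes. Steep falls were found in neighbouring minus-strand genes left of the arrays. These included SiRe_0756 (hypothetical protein, 56.3 ± 11.7 to 9.48 ± 1.4 CPM, log2 −2.56 ± 0.21, edgeR adjusted p = 0.000192), SIRE_RS03820 (phosphomethylpyrimidine synthase, −2.44 ± 0.23) and SiRe_0753 (ketol-acid reductoisomerase, an enzyme of branched-chain amino acid synthesis, −2.16 ± 0.21). The low-count feature cds783 between them, chosen after its value was seen, gave −3.04 ± 0.44. SiRe_0749, a glutamate dehydrogenase, fell from 381 ± 5.04 to 128 ± 21.3 CPM (log2 −1.57 ± 0.12, edgeR adjusted p = 0.000192; chosen after seeing its value). The gene aceA, encoding the glyoxylate cycle enzyme isocitrate lyase, fell from 202 ± 36.3 to 98.2 ± 6.91 CPM (−1.04 ± 0.14, edgeR adjusted p = 0.00441). On the right flank SiRe_0784, an MFS transporter, fell 3.21-fold. The hypothetical protein gene SiRe_0783 (log2 −1.59), the AbrB family regulator SiRe_0777 (−1.09) and the endoglucanase SiRe_0791 (−0.65) also fell, although DESeq2 did not call SiRe_0777 (adjusted p = 0.0661). Some features within the segment were not called. The malate synthase SiRe_0741 gave −0.25 ± 0.11, and the adjacent SiRe_0750, SiRe_0751 and SiRe_0752 gave −0.10 ± 0.16, −0.00 ± 0.17 and 0.15 ± 0.29. All 4 were chosen after their values were seen.

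**Figure D2:**
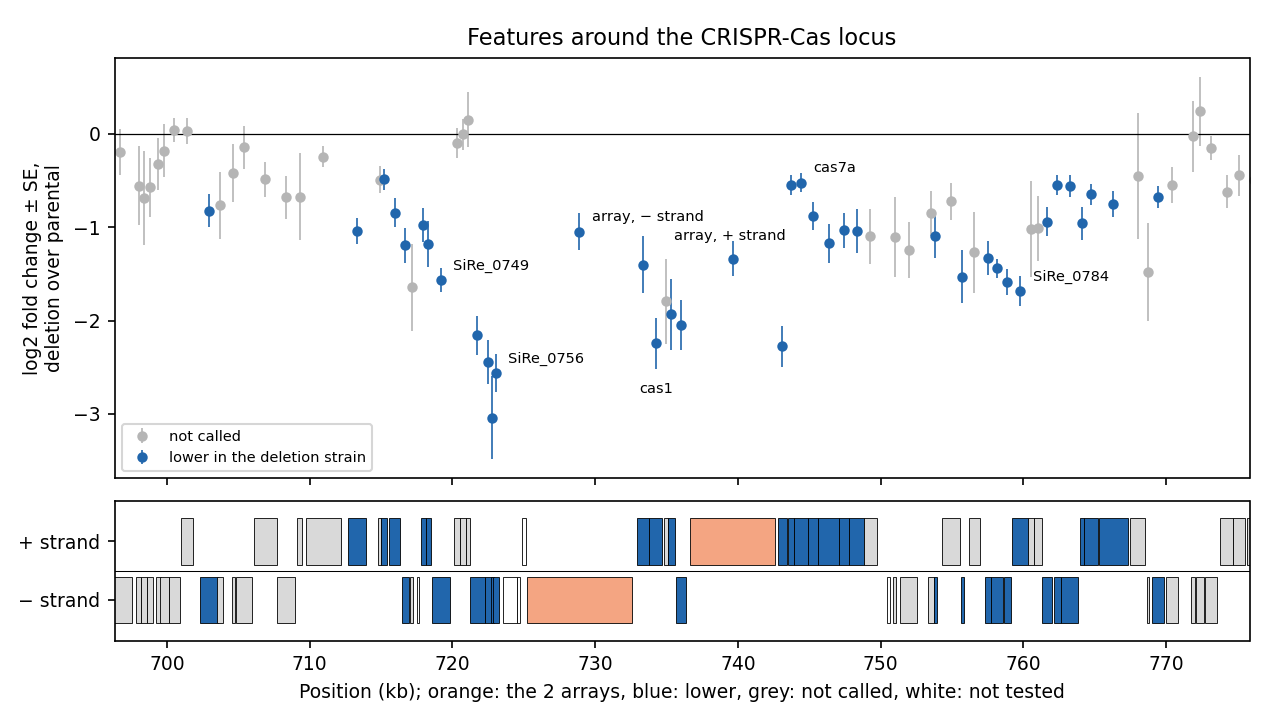
Top, log2 fold change ± SE (deletion over parental strain, 2 libraries each) of features around the CRISPR-Cas locus against position in kb, blue where lower and grey where not called. Bottom, the features on each strand, with the 2 arrays in orange and untested features in white; 38 of 61 tested features between 702344 and 769850 were lower, on both strands.

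Outside the segment, pcn (SiRe_1594, 1477470 to 1478249, minus strand) fell from 305 ± 13.3 to 117 ± 3.52 CPM (log2 −1.38 ± 0.10, edgeR adjusted p = 0.00014). SiRe_1595 (1478312 to 1479616, plus strand) starts 62 bp away in the opposite direction and rose from 213 ± 16.8 to 745 ± 7.67 CPM (1.80 ± 0.10, edgeR adjusted p = 3.83e-05). Both were called with each library left out in turn. The other falls outside the segment included those in SIRE_RS14785 (hypothetical protein, −2.12), the integrase SiRe_1325 (−2.04; DESeq2 adjusted p = 0.0513), cds867 (hypothetical protein, −1.83) and the transposase SiRe_0633 (65.8 ± 5.13 to 28.4 ± 2.05 CPM, −1.21). SiRe_0433, annotated as a nickel transporter, gave −1.34. Smaller falls were found in SiRe_2034 (alcohol dehydrogenase, −0.56), SiRe_2454 (N-acetyltransferase, −0.51) and SiRe_1975 (molybdenum cofactor biosynthesis protein, −0.51). These 4 were chosen after their values were seen. Copies of transposases and integrases can share reads, so those values are uncertain.

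Among the 181 tested transporter genes, 9 rose and 3 fell by edgeR's quasi-likelihood test, and 11 rose and 3 fell when adjusted over the list alone. Of the 3 that fell, 2 lie in the segment. Raised genes were more frequent in the list than among other tested genes (Fisher's exact test, two-sided, p = 0.00039, Benjamini-Hochberg adjusted p = 0.00702). That test treats genes as independent, although some raised members are neighbours, such as SiRe_1514 to SiRe_1516. Runs of adjacent members were not counted once for this list. The camera test gave adjusted p = 0.113 with a preset and adjusted p = 0.993 with an estimated correlation. The largest rise in the list was in SiRe_1516, the substrate-binding protein of an ABC transporter, from 253 ± 45.6 to 545 ± 14.1 CPM (1.10 ± 0.13, edgeR adjusted p = 0.00192). Its neighbours SiRe_1515, annotated as an iron ABC transporter permease, and SiRe_1514, an ATP-binding protein, rose by 0.96 and 0.93 on the log2 scale. SiRe_2190, a further substrate-binding protein, rose from 383 ± 9.99 to 760 ± 110 CPM (0.99 ± 0.12, edgeR adjusted p = 0.00192), and so did the permease SiRe_2186 (1.09) and the sugar-binding protein cds2207 (0.74). In 7 of the 9 raised transporter genes parental library 2 lay above parental library 1. Without parental library 1 the number of raised transporters was 7, and without deletion library 2 or 3 it was 3 or 0.

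The remaining genes among the 12 largest rises were SiRe_0589 (1.30 ± 0.24, edgeR adjusted p = 0.0203; 0.113 by DESeq2), SiRe_0269 (1.09), SiRe_0112 (precorrin-8X methylmutase, 1.04), SiRe_2314 (1.03), SiRe_1081 (annotated as a nickel transporter, 0.99) and SiRe_1957 (0.93). SiRe_0589, SiRe_0269 and SiRe_2314 encode hypothetical proteins. SiRe_1957, whose product text names a flagellar hook protein, was the only member of the 12 archaellum and pili genes called by edgeR (660 ± 160 to 1261 ± 191 CPM, adjusted p = 0.0182). DESeq2 called it and SiRe_1879 higher (DESeq2 adjusted p = 0.0122 for SiRe_1879). Adjusted over the list alone, 2 rose and 1 fell.

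**Figure D3:**
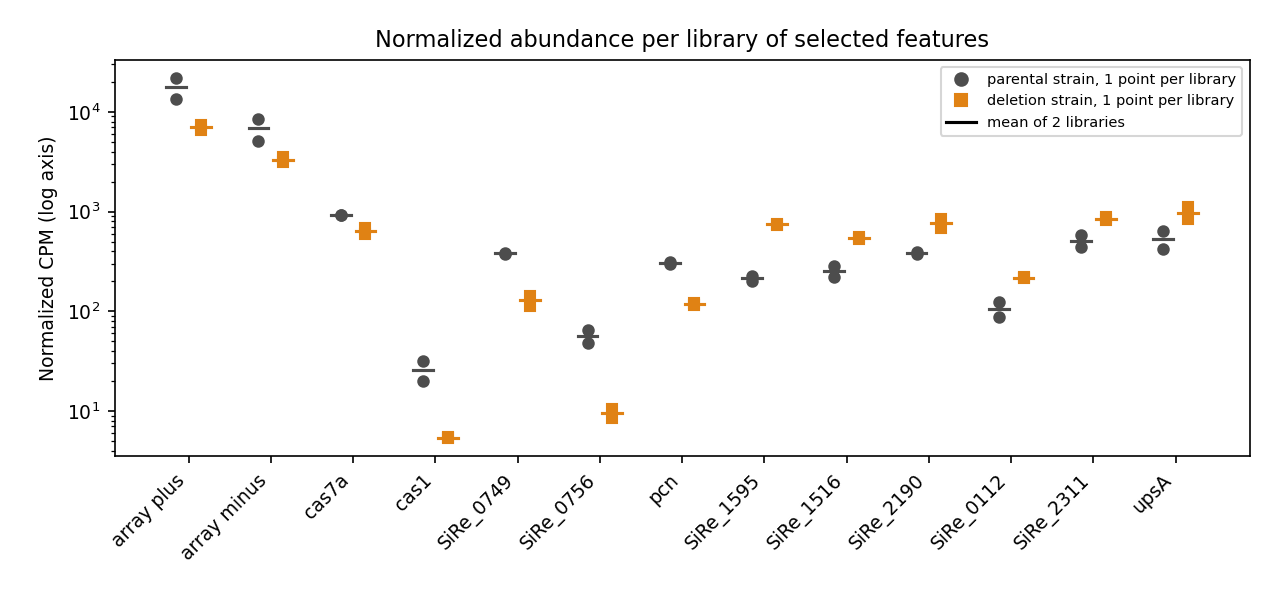
CPM per library on a log axis for selected features, with parental libraries as grey circles, deletion libraries as orange squares and horizontal lines at the mean of 2. The arrays, cas genes, SiRe_0749, SiRe_0756 and pcn are lower in both deletion libraries, and SiRe_1595 and the 5 features to its right are higher.

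The other lists held few called genes by edgeR's quasi-likelihood test, and none held more of them than other tested genes (Fisher's exact test, lowest adjusted p = 0.819 over both directions). Mobile elements (94 tested) had 3 lower members, toxin-antitoxin genes (18) 1 and transcription regulators (91) 2, in each case with at least 1 in the segment. Adjusted over the list alone, these were 3, 1 and 1. Over the 18 tested lists, fry called 0 for a shift in a single direction (lowest adjusted p = 0.422) and 8 for change in either direction. For mobile elements camera gave an adjusted p = 0.0387 downward with a preset correlation and adjusted p = 0.993 with an estimated correlation. Of 30 replication and repair genes, pcn fell and dps rose (0.64 ± 0.11, edgeR adjusted p = 0.0184; its product text reads DNA polymerase, while its symbol is that of a ferritin-like DNA protection protein). Adjusted over the list alone, 2 fell and 2 rose. Of 16 genes on the citric acid cycle list only aceA changed, which the product text placed there although it encodes the glyoxylate cycle enzyme isocitrate lyase. Of 17 glycoside hydrolases only SiRe_0791 changed, and of 15 genes of lysine, arginine and branched-chain amino acid synthesis only SiRe_0753. All 3 genes lie in the segment. Adjusted over the list alone, 1, 1 and 3 fell, and 1 gene of the last list rose. DESeq2 also called ilvD of that list higher (adjusted p = 0.0481). Of 52 sulfur and iron-sulfur genes, 2 rose, SiRe_2310 (phosphoadenosine phosphosulfate reductase, 0.72) and SiRe_2307 (sulfite exporter family, 0.70), and the ferredoxin SiRe_0532 fell (−0.77). Adjusted over the list alone, 5 rose and 1 fell, and DESeq2 called 4 higher and 1 lower. DESeq2 called 3 mobile elements lower and 1 higher, and 11 transporters higher and 3 lower.

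No member was called in 9 lists, with 193 genes together, of which 7 had an unadjusted p under 0.05 and 1 was called by DESeq2 (edgeR's lowest adjusted p = 0.0663). These lists were ribosomal proteins (65 tested), transcription machinery (26), translation factors and aminoacyl-tRNA synthetases (33), the respiratory chain (29), chaperones and proteasome (14), pyrimidine metabolism (19), cell division (4), chromatin proteins (1) and structural and small RNAs (2). Adjusted over the list alone, 1 cell division gene, the Cdc6-type SiRe_0002 (−0.39 ± 0.10), fell and no other member changed. The members of the last list, endA and SiRe_1718, encode tRNA splicing enzymes and not RNAs, and the viral list matched 0 features. The abundant chromatin proteins, looked up after the list caught none of them by product text, gave −0.21 ± 0.10 (alba1), −0.13 ± 0.09 (alba2) and −0.38 ± 0.14 (cren7), none called.

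The labels give both strains a pyrEF and lacS background, so the genotypes imply no difference at pyrE. It had 13.8 ± 1.11 CPM in the parental and 10.96 ± 0.141 CPM in the deletion strain (−0.33 ± 0.21, edgeR adjusted p = 0.640). This value does not check the deletion. Of the 10 genes next to cbp1, 5 on each side, none was called by edgeR's quasi-likelihood test, with log2 fold changes of −0.65 to 0.14 and a lowest adjusted p = 0.0693. Of them, 2 had an unadjusted p under 0.05, and DESeq2 called 1, SiRe_1550 (−0.38 ± 0.09, DESeq2 adjusted p = 0.0284).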

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

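Of these alternatives, leaving out the segment, the lists chosen later and the authors' deposited values were chosen after seeing the data. No paired analysis was possible because the count columns are numbered 1 and 2 for the parental strain and 2 and 3 for the deletion strain, so the groups share a single number. The replicate block, the alternatives meant for normalized values or for a table of comparisons alone, and those for cbp1 were not run for the same reason or because no such value was used. Of the 85 calls, 79 were shared with DESeq2, 85 with RLE factors, 69 with upper quartile factors, 84 without a filter, 76 with a mean of 50 counts (6 were not tested) and 85 with the other library sizes, and none changed direction. Without a parental library, 64 (library 1) and 85 (library 2) were called again, and without a deletion library 16 (library 2) and 8 (library 3). A lone library was assumed to vary like the other group.

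The count of 51 lower genes was 18 at an adjusted p under 0.01, 32 with at least a 2-fold change, 24 with runs counted once and 13 without the segment, and 7 to 127 with a library left out. The 34 higher genes were 56 by DESeq2 and in the authors' deposited table, 9 at 0.01, 7 at 2-fold and 1 to 115 with a library left out. The 38 lowered features of the segment were 14 at 0.01, 24 at 2-fold and 6 to 48 with a library left out. The 11 lowered cas genes were 3 at 0.01 and 1 to 12 with a library left out, and the 9 raised transporters 4, 2 at 2-fold and 0 to 18. Lists with more called members numbered 2, or 1 at 2-fold and 0 to 3 with a library left out. The Fisher p of the CRISPR-Cas list ranged from 4.74e-09 to 0.0785 with a library left out. DESeq2 called 1 neighbour of cbp1, and leaving out a library gave 0 to 1.

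The minus-strand array kept its direction throughout, at −1.04 by DESeq2 (adjusted p = 0.108), −1.05 and not called at 0.01, and −1.38 to −0.62 with a library left out (adjusted p over all alternatives 3.38e-06 to 0.336). The plus-strand array gave −1.64 to −0.94 and pyrE −0.41 to −0.25. Among the named genes, the sign changed only in some that were not called. SiRe_0751 gave 0.0027 with upper quartile factors, 0.0013 without a filter and 0.00042 with the other library sizes. With a library left out, the ranges were SiRe_0750 −0.29 to 0.13, SiRe_0751 −0.20 to 0.23, SiRe_0752 −0.082 to 0.46, SiRe_1214 −0.012 to 0.32, SiRe_1542 −0.70 to 0.012, SiRe_1543 −0.25 to 0.41, SiRe_1549 −0.054 to 0.28, alaXM −0.087 to 0.13, SiRe_1740 −0.17 to 0.0083 and SiRe_1885 −0.13 to 0.11. The cause of these shifts was not tested. Some features were weak: cas2, which was not called, and SiRe_1325, which edgeR called lower, had under 5 CPM in every library. The effect of depth was not tested.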

Other observations

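Some genes of 4 groups outside the lists written beforehand rose in the deletion strain, and these groups, like the tests of chance placement, of parental library 1, of copy number, of features between the arrays or opposite to them and of the culture axis, were chosen after the results were seen. Of 15 genes of corrinoid and tetrapyrrole synthesis, 5 rose. Besides SiRe_1595 these were the adjacent cbiD (0.75 ± 0.11), SiRe_0111 (0.76 ± 0.11) and SiRe_0112 (1.04 ± 0.15), of the corrin ring pathway, and SiRe_2312 (0.74 ± 0.16), a uroporphyrinogen-III methyltransferase. Of 4 riboflavin genes, SiRe_1597 (0.71 ± 0.16) and ribC (0.62 ± 0.13) rose, and they follow SiRe_1595 on its strand together with the raised GTP cyclohydrolase gene SiRe_1600 (0.66 ± 0.14). Of 4 genes of sulfate assimilation, SiRe_2310 and SiRe_2311 rose. SiRe_2311, whose product text reads nitrite reductase, went from 512 ± 98 to 848 ± 39.7 CPM. Of 89 ABC transporter genes, 8 rose and none fell, with a median log2 fold change of 0.07 over all of them. The groups were formed around raised genes, so no test of these counts is given. Without parental library 1 the numbers raised were 4, 0, 2 and 6. Parental library 2 lay above parental library 1 in 4 of the 5 corrinoid genes, both riboflavin genes, both sulfate genes and 6 of the 8 ABC transporter genes.

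Also chosen after seeing the data, the genes upsA (531 ± 152 to 977 ± 185 CPM, 0.88 ± 0.19, edgeR adjusted p = 0.0340) and upsB (0.61 ± 0.13, edgeR adjusted p = 0.0340), which encode pilins of the UV-inducible pili of Sulfolobales, rose. The neighbouring upsF (0.52 ± 0.13, edgeR adjusted p = 0.0656) and SiRe_1879 (0.61 ± 0.16, edgeR adjusted p = 0.0838) were not called by edgeR, but DESeq2 called both higher (DESeq2 adjusted p = 0.0481 and 0.0122). The archaellum is the rotating filament used for swimming. Its genes SiRe_0122 (2.27 ± 0.780 to 0.620 ± 0.234 CPM) and SiRe_0119 (5.17 ± 0.484 to 3.02 ± 0.0146 CPM) were weakly expressed and not called (edgeR adjusted p = 0.149 and 0.310).

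The segment of lowered genes around the CRISPR-Cas locus was found in these data and tested on the same data, so what follows is a hypothesis, and without deletion library 2 or 3 only 10 or 6 of its features were called. Chance placement is argued against by shuffling the order of the 943 runs of features on a strand and joining lowered features by the same rule: 0 of 10000 shuffled orders gave a group of 38 anywhere (permutation test, p = 0.0001), where the largest group was 17. Read-through of array transcripts is argued against between the arrays only for transcripts on the strand given for each array. The stretch lies upstream of both, and 4 of 5 tested features were lower there (exact 95% interval 28.4% to 99.5%). Transcripts from the opposite strand of an array would run toward this stretch, and they were not tested. The interval treats the 5 features as independent, although cas4a, cas1, cas2 and SiRe_0763 lie next to each other on the plus strand. On the flanks it stays open: 14 of the 36 lowered genes lie there on the strand opposite to the array beside them, but the strand setting of the counting is not given in the sources used here, and features downstream on the strand of an array differed from the other flanking features by −0.17 in median log2 fold change (−1.02 over 29 against −0.85 over 25, two-sided permutation test, p = 0.405). A single change of DNA copy number would give the members a shared fold, yet 19 of 38 intervals (moderated degrees of freedom, 95%) left out the pooled −1.05. With intervals on the 2 residual degrees of freedom, which were computed first, 10 of 38 did so. The exact interval of the share was 33.4% to 66.6% with the moderated and 13.4% to 43.1% with the residual degrees of freedom. Both lie above the share that 95% intervals would miss if all members had a single fold. A copy number change alone is therefore argued against for the members called lower, with features treated as independent. Only members called lower were used, and the 23 features of the segment not called were left out. In the fit without parental library 1, the largest group of lowered features by the same joining rule had 31 features, all within the segment. Of 10000 shuffled orders, 0 gave such a group (permutation test, p = 0.0001). This fit took the spread from the deletion libraries alone. With the spread of both parental libraries fewer features were called lower, and where these lie was not tested. Parental library 1 alone is therefore argued against only by where the calls lie with the deletion spread. It stays open for how many features fell. A second mutation in the deletion strain, a difference in culture state and an effect of losing Cbp1 on this part of the chromosome stay open and untested.

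The 34 raised genes were compared between libraries of a strain to ask whether they follow an axis along which cultures vary anyway. Parental library 2 exceeded parental library 1 in 29 of 34, with a median log2 ratio of 0.27, outside the −0.08 to 0.08 of expression-matched random lists, while between deletion libraries the median ratio was −0.05, within −0.06 to 0.06. The 51 lowered genes also shifted between the parental libraries in the direction of the strain difference, with a median log2 ratio of −0.13 (outside −0.10 to 0.07; above 0 in 17 of 51), and not between the deletion libraries (−0.02, within −0.09 to 0.05). A culture difference could therefore account for part of the rises and falls, and it cannot be told apart from the deletion with 2 libraries a strain. Parental library 1 alone is argued against for SiRe_1595, which was called with each library left out, and stays open for the rises as a set. Without it the fit called 30 genes higher, 23 of the 34 among them, but took the spread from the deletion libraries alone, and with the spread of both parental libraries 5 were called. Without deletion library 2 or 3 the fit called 4 or 1 higher. An effect of the missing protein on these genes remains open and was not tested separately.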
